A study of Mus musculus with 8 samples.

How the data were processed

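ZFP281 chromatin immunoprecipitation was sequenced in 3 early lesion (EL) and 3 primary tumour (PT) sphere cultures of FvB mice, with 1 input per group, as paired reads of 150 bp, per the labels' protocols. The same protocol text also names an RNA extraction kit, which does not belong to this assay. Per the submitters' processing notes, the genome build was mm10 and the tools included Bowtie2 2.3.4.3 and Picard. The peak caller, its version and whether the inputs served as background are not given in the sources used here. The authors deposited 1 list per ZFP281 library, so summits were called per sample and not on pooled samples. Each line is a position of 1 bp with a score. The lowest score of every list lies above 1.30, the −log10 of 0.05, from 1.303 in EL replicate 3 to 1.551 in PT replicate 2. For this reason the deposited score was read as the −log10 of a q-value. That reading comes from the values, not from a label. The score is the authors' own and was used to rank summits within a list, as a percentile of that list, and as a limit of 5 or 10 applied to all lists in 2 alternatives.

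Read depth is unknown, so no value could be scaled by it. A longer list can reflect more reads, a better enrichment or more binding. Lists of equal length, the 2897 top-scoring summits of each library, were therefore an alternative for most comparisons. Among those made on full lists only were the summit number and the shares in gene bodies, between genes and over 5 kb from a boundary. The share of the regions of 1 library found in another was also taken from full lists only. The share of summits near a gene boundary had a 95% Wilson interval per library, from 32.1% to 34.1%, 27.3% to 28.7% and 33.0% to 35.2% in EL replicates 1, 2 and 3, and from 38.0% to 41.6%, 36.0% to 39.0% and 36.2% to 38.7% in PT replicates 1, 2 and 3. These intervals cover counting error only.

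Summits on chromosomes 1 to 19, X and Y were used. Positions are 1-based. Summits of any library at most 200 bp apart were merged into a region. Genes came from a RefSeq table of assembly GRCm38, the mm10 build, with 21887 protein-coding genes. The table gives start and end without strand, exons or sequence, so the planned distance of 1 kb to a transcription start site became 1 kb to either gene boundary, and a boundary called lower or upper is the one with the smaller or larger coordinate. A summit counted for every gene within reach. Shares in exons and introns, motif shares, GC content, lists matched on GC content and shuffled sequences were planned and not run for want of sequence. Gene lists comprised 14 lists of 387 symbols, all found in the table, and 7 gene families defined by symbol, 21 in all.

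Comparisons used the exact permutation test of 3 against 3 libraries, two-sided, with 20 relabellings and a smallest p of 0.1, so no such test could pass 0.05. A gene was in the consensus of a group when bound in at least 2 of its 3 libraries. List genes in each consensus were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 21 lists. This test runs across genes, which are not independent replicates. It also takes no account of GC content, a planned control that was not run, so a call alone cannot be read as targeting of a pathway. The labels call the libraries biological replicates and do not say which animals they came from. At most 81 summit positions were identical between any pair of lists, so no pair of lists was the same.

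The genes named were set by rule. In each of 3 classes (all 6 libraries, all 3 EL and no PT, all 3 PT and no EL) the 10 genes with the highest lowest percentile were named, with the 5 leading regions over 5 kb from any boundary, Zfp281, and up to 4 examples per list, those bound in the most libraries and then by percentile. Some examples that the rule names are not reported here. Further list members were chosen after their values were seen, namely those named beyond 4 per list or out of that order. Lists, tests, naming rule and most alternatives were fixed before the data were examined. Alternatives were stricter scores (at least 5 and at least 10), equal list lengths, other sequences, autosomes, each library left out, merging at 50, 500 and 1000 bp, windows of 500 bp and 5 kb, gene bodies, all annotated genes, other consensus rules and a replicate block. Added after seeing the data were random lists matched on gene length, the test of the difference between consensus sets, and regions above score percentiles.

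The steps were tested on simulated data. For the consensus regions, 1500 shared, 1000 EL-only and 200 PT-only regions were planted, and 1500, 998 and 199 were recovered. Planted summits of a region always lay within the merging distance and none was dropped, so near-complete recovery was set in advance. The recovered numbers are class totals, not matched to the planted positions. They check the counting and say nothing about accuracy on the deposited lists. For list occupancy in the EL consensus over 21887 genes, a planted list of 30 genes drawn with a weight of 4 for bound genes was called in 68.5% of 200 runs, and a list of random genes was called in 3% of the runs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.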

Results

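Chromatin immunoprecipitation sequencing of ZFP281, a zinc finger transcription factor known from the control of pluripotency, was carried out on spheres grown from the MMTV-HER2/Neu mouse, a strain in which the HER2/Neu oncogene is expressed in the mammary gland. Spheres came from early lesions (EL; animals of 14 to 18 weeks without a palpable tumour) or from primary tumours (PT; animals older than 20 weeks), after 7 days in mammosphere medium on plates that prevent attachment. Each group had 3 ZFP281 libraries, labelled as biological replicates, and 1 input library. The tissue label reads mammary lung for the EL samples and breast tumor for the PT samples, and the cells of both groups are labelled as breast cancer cells. For each ZFP281 library the deposited data are a list of binding summits, each a position of 1 bp with a score, and the inputs were not analysed here. Sequencing depth is unknown, so the number of summits in a list cannot be set against the number of reads behind it. The comparison implied by the design asks where ZFP281 bound in early lesion spheres and in primary tumour spheres.

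ZFP281 summits were more numerous in the early lesion libraries. The lists held 8588, 15770 and 7055 summits on chromosomes 1 to 19, X and Y in EL replicates 1, 2 and 3, and 2897, 4030 and 6033 in PT replicates 1, 2 and 3. The means were 10471 ± 4653 (SD, n = 3) and 4320 ± 1588 (SD, n = 3), a ratio of 2.42. The groups did not overlap, and the exact permutation test gave p = 0.1 (two-sided), the smallest p that 3 against 3 libraries allow. Without EL replicate 2 the ratio was 1.81.

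**Figure D1:**
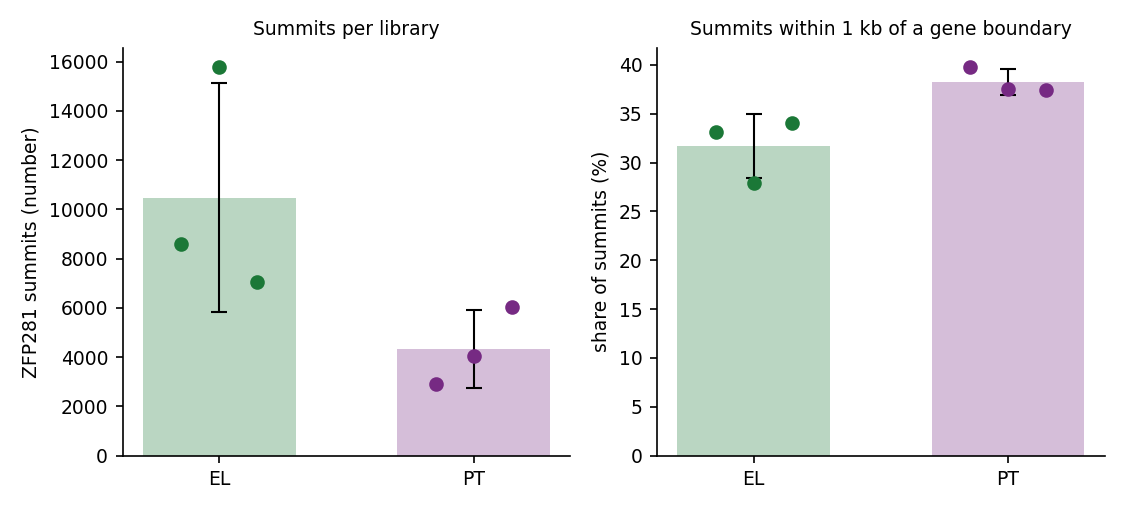
Left, number of ZFP281 summits per library; right, share of summits within 1 kb of a protein-coding gene boundary (%); bars are group means, error bars are SD (n = 3) and points are libraries. EL libraries held between 7055 and 15770 summits and PT libraries between 2897 and 6033, while the boundary share was 31.7% in EL and 38.2% in PT.

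A larger part of the PT summits lay close to genes. Within 1 kb of either boundary of a protein-coding gene lay 38.2% ± 1.32 (SD, n = 3) of the summits in PT and 31.7% ± 3.29 (SD, n = 3) in EL, a difference of -6.53 percentage points, EL minus PT (exact permutation p = 0.1, two-sided). Deeper in gene bodies lay 41.0% ± 1.32 of EL and 37.5% ± 0.757 of PT summits, and between genes 27.3% ± 2.08 and 24.2% ± 0.847 (SD, n = 3 each). Summits over 5 kb from every gene boundary made up 48.5% ± 3.93 in EL and 41.3% ± 1.62 in PT. In lists limited to the same number of top-scoring summits, 2897 per library, the boundary difference was -0.127 percentage points (exact permutation p = 1, two-sided).

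Libraries of the same group shared more binding regions than libraries of different groups. Summits of any library at most 200 bp apart were merged into 19317 regions. The mean Jaccard index, the number of shared regions over the number in either list, was 0.440 for the 3 pairs within EL and 0.453 for the 3 pairs within PT, against 0.263 for the 9 pairs between groups. After moving 1 list by 10 kb, the index was at most 0.00381. The within-group mean exceeded the between-group mean by 0.184 (exact permutation p = 0.1, two-sided, the smallest possible). At equal list lengths the means were 0.594, 0.531 and 0.357, and the lowest pair within a group, at 0.518, lay above the highest pair between groups, at 0.387. In full lists a mean of 70.6% of the regions of a PT library were also found in a given EL library, and 30.9% of those of an EL library in a given PT library.

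**Figure D2:**
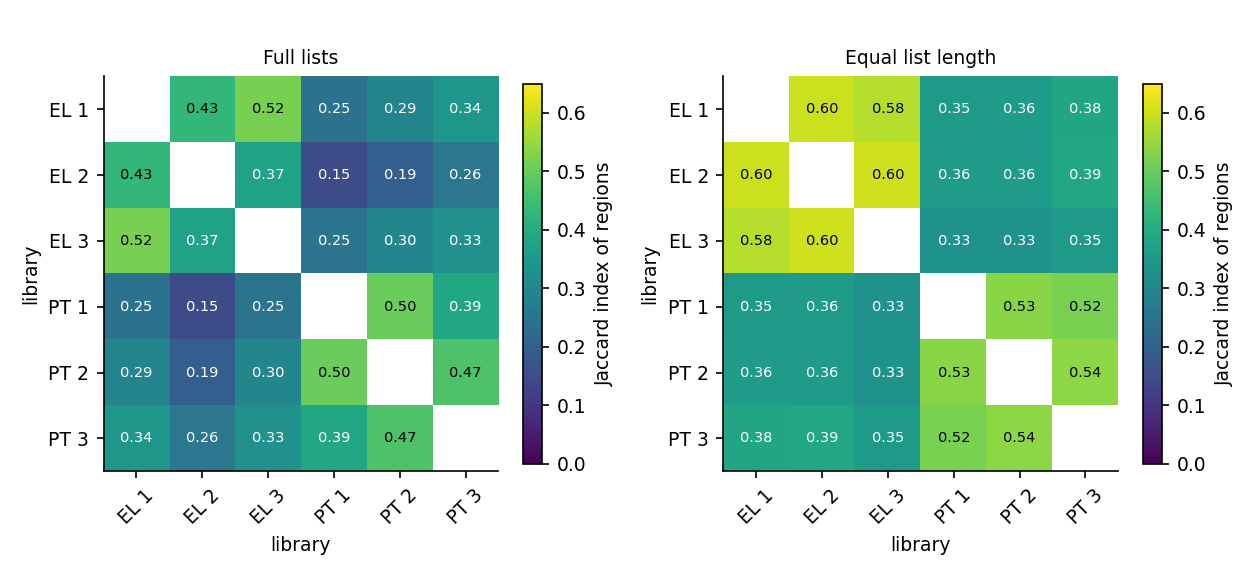
Jaccard index of binding regions for each pair of libraries, from full lists (left) and from the 2897 top-scoring summits of each library (right); rows and columns are libraries and the colour scale is the index. In the right panel the pairs within a group reached 0.518 or more and the pairs between groups 0.387 or less.

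A shared set of 1573 regions was found in all 6 libraries, 1937 in every EL and no PT library, and 136 in every PT and no EL library. The imbalance between the last 2 classes moved with list length, since equal list lengths gave 442 EL-only and 381 PT-only regions. Of the 19317 regions, 6436 were found in EL replicate 2 alone. Left out 1 at a time, libraries moved the EL-only number to between 1995 (without PT replicate 1) and 3409 (without EL replicate 3), and the PT-only number to between 147 (without EL replicate 3) and 315 (without PT replicate 1). Leaving out a library loosens both class rules, so these numbers could hardly fall.

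The genes bound at a boundary in all 6 libraries with the highest lowest score percentile were, in rank order, Sumo3, Kmt2a, Pcbp1, Chd3, Kmt2e, Kmt2b, Zbtb32, Tbl1xr1, Ndor1 and Tmem203. Kmt2a and Kmt2b encode histone H3 lysine 4 methyltransferases, and Chd3 a remodeller of the NuRD complex. The Kmt2a region, on chromosome 9 from 44881434 to 44881513 (mm10), lay 121 bp from the upper gene boundary at 44881352, and its lowest percentile in any list was 99.8. Kmt2b and Zbtb32 shared 1 region (chromosome 7, 30588750 to 30588785), as did Ndor1 and Tmem203 (chromosome 2, 25255435 to 25255466). The Tbl1xr1 region with the most libraries held 4 of them. Zfp281 itself carried a summit in all 6 libraries, in a region of chromosome 1 from 136625513 to 136625780, 745 bp from the lower gene boundary, with a percentile of 15.2 in PT replicate 3 and at least 77.2 in the other 5 lists.

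In all 3 EL and no PT library, 424 genes carried a boundary summit. The highest ranked were Ms4a4d, Shmt2, Cdh11, Chid1, Gng8, Pros1, Lrp2bp, Col5a1, En1 and Fam111a. Cdh11, which encodes the mesenchymal cadherin 11, had its region on chromosome 8 from 102785133 to 102785176, 339 bp from the upper gene boundary, with a lowest percentile of 89.0 in the EL lists. Col5a1, a fibrillar collagen gene, had its region on chromosome 2 from 27886303 to 27886363, 48 bp from the lower boundary, with a lowest percentile of 86.1. The region at Shmt2, an enzyme of mitochondrial one-carbon metabolism, on chromosome 10 from 127516650 to 127516702, also lay within 1 kb of Ndufa4l2.

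Only 10 genes showed the opposite pattern, a boundary summit in all 3 PT and no EL library, namely Orai1, Stx6, Csn3, Igsf9, Epb41l1, Rnf39, Gm42323, Kdf1, Barx2 and Strbp. Csn3 encodes the milk protein kappa-casein, and its region on chromosome 5 from 87924810 to 87924876 lay 736 bp from the lower gene boundary with a lowest percentile of 50.6 in the PT lists. Gm42323 and Kdf1 shared 1 region (chromosome 4, 133519078 to 133519096). Lists of equal length gave 83 genes in EL only and 74 in PT only, so the imbalance of 424 to 10 also depended on list length. The number of genes bound per library was 3357 ± 1055 in EL and 1782 ± 601 in PT (SD, n = 3; ratio 1.88, exact permutation p = 0.1, two-sided), and the ratio was 1.02 with equal list lengths. A total of 960 genes were bound in all 6 libraries. Without EL replicate 3 the EL-only number was 757, without PT replicate 3 it was 721 and without EL replicate 1 it was 637, while the PT-only number was 32 without PT replicate 1 and 24 without EL replicate 2. With a library left out the class rules are looser, so neither number could fall.

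**Figure D3:**
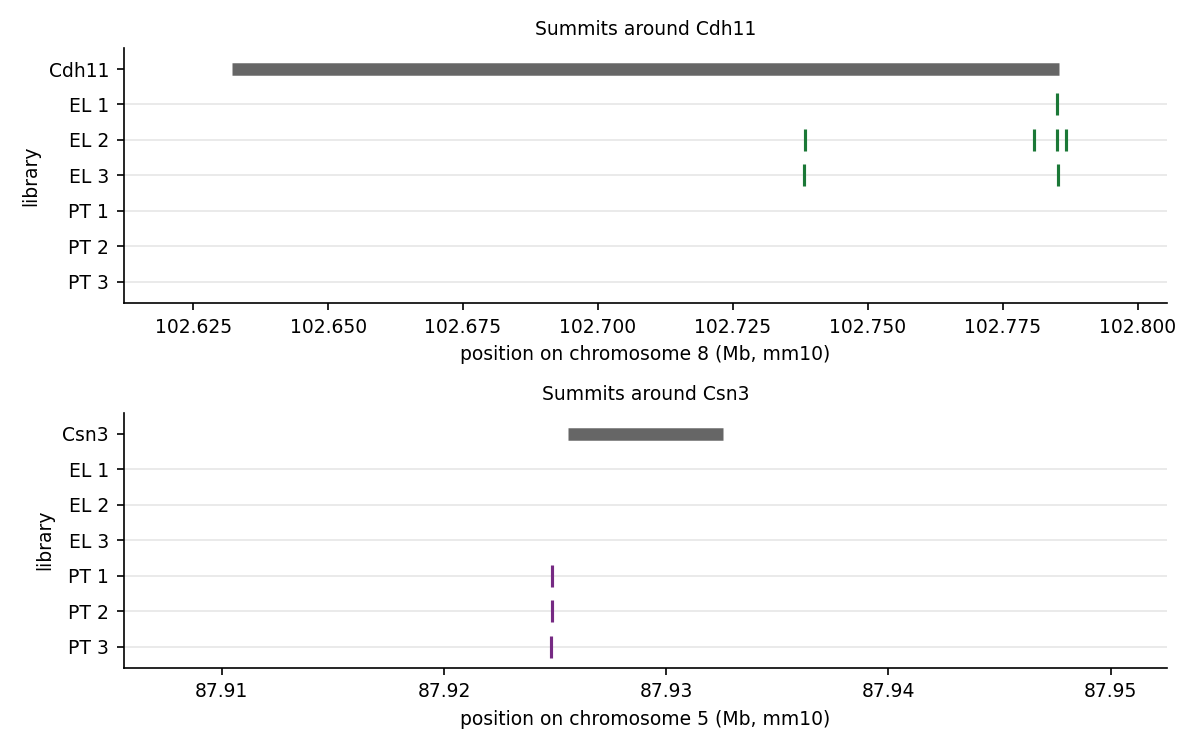
Position of every ZFP281 summit (vertical ticks) in each library around Cdh11 on chromosome 8 and Csn3 on chromosome 5 (mm10, Mb); the grey bar is the gene and the window extends 20 kb to each side. A summit near the upper boundary of Cdh11 was present in the 3 EL libraries and no PT library, and a summit beside Csn3 in the 3 PT libraries and no EL library.

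Far from gene boundaries, although often inside genes, 496 of the 1573 regions found in all 6 libraries (31.5%), 1154 of the 1937 EL-only regions (59.6%) and 92 of the 136 PT-only regions (67.6%) lay over 5 kb from every protein-coding gene boundary. The leading shared ones lay inside Srrm2 (chromosome 17, 23803497 to 23803534), nearest to Atf7ip, Skor1 and Lrrc74a, and inside Nfic. The leading EL-only ones lay inside Plxna1 (chromosome 6, 89345084 to 89345124) and Slc6a7, and nearest to Pim1, P2ry6 and Fzd2. The leading PT-only ones lay inside Erbb3, the gene of a HER2 partner receptor (chromosome 10, 128584541 to 128584650), Faim2, Unc80, 2900026A02Rik and Rara. The 3 classes also differed in score. Median percentiles of shared regions were 83.3 to 93.2 in the EL lists and 65.8 to 83.9 in the PT lists. Those of EL-only regions were 47.6 to 73.3, and those of PT-only regions 42.6 to 64.4. The shares over 5 kb from a boundary were not computed at equal list lengths, so the part of score in them was not tested.

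Genes of epithelial to mesenchymal transition (EMT) and the mesenchymal state carried boundary summits in EL more often than in PT. Of the 36 genes of this list, 47.2% ± 5.56 were bound per EL library and 7.41% ± 4.24 per PT library (SD, n = 3, exact permutation p = 0.1, two-sided, adjusted p = 0.263 over 21 lists). Other lists reached the same exact permutation p and adjusted p in full lists, so these values are not particular to EMT genes. Ribosomal protein genes were among them, at 11.9% ± 2.57 in EL and 5.35% ± 0.713 in PT. In all 3 EL and no PT library were 10 genes of the EMT list, among them Cdh11, Col5a1, Itga5 and Col1a1, and also Vim, Axl, Cdh2 and Zeb2. The lowest EL percentiles of Vim, Axl, Cdh2 and Zeb2 were 48.7, 47.2, 24.9 and 6.14. At equal list lengths these genes were bound in 1, 2, 0 and 0 EL libraries, and Cdh11, Col5a1, Itga5 and Col1a1 in 3 each. The EMT transcription factor genes Twist1, Snai1 and Zeb1 were bound in 3 EL libraries and in 2, 1 and 1 PT libraries, Itgb1 in 3 EL and 1 PT libraries, and Sox4 was bound in all 6 libraries. Bound in at least 2 EL libraries were 17 genes (Fisher's exact test against all other protein-coding genes, odds ratio 5.44, adjusted p = 8.8e-06), and in at least 2 PT libraries 2 genes (odds ratio 0.729, adjusted p = 1). In lists of equal length the numbers of bound genes were 8, 10 and 10 in EL and 1, 3 and 2 in PT. A test of the difference, added after seeing the data, set genes bound in at least 2 EL and no PT library against genes bound in at least 2 PT libraries, and gave an odds ratio of 10.04 (Fisher's exact test, adjusted p = 0.00426), with adjusted p between 9.0e-05 and 0.149 over 16 alternatives, 2 of which lost the call. Without PT replicate 3 its adjusted p was 0.0673 (Fisher's exact test). Of the 1633 genes bound in at least 2 PT libraries, only 38 had no EL summit. The test thus set EL-only genes mostly against genes bound in both groups, and not EL against PT.

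Fibroblast and adipocyte markers, tested as genes of other cell types, were bound in 31.7% ± 11.5 of 20 genes per EL library and 3.33% ± 2.89 per PT library, and collagen genes in 13.6% ± 7.87 of 44 and 0% (SD, n = 3; exact permutation p = 0.1 for each, adjusted p = 0.263). The bound collagen genes of at least 2 EL libraries were Col5a1, Col6a2, Col1a1 and Col1a2. All protein-coding genes were bound at 11.7% to 20.8% per EL library and 5.76% to 11.1% per PT library. Examples of the fibroblast and adipocyte list were Pdgfra, Plin1, Col6a2 and Dcn, each bound in 3 EL libraries and in 1, 1, 0 and 0 PT libraries. The EMT and collagen lists share 4 genes, and the fibroblast and collagen lists share 2. Neither list passed Fisher's exact test in the EL consensus (adjusted p = 0.112 and 0.636), with passes in 3 and 1 of 16 alternatives. Neither passed the test of EL-only against PT genes (Fisher's exact test, adjusted p = 0.0843 each). At equal list lengths that test gave adjusted p = 0.0155 for fibroblast and adipocyte markers and 0.00301 for collagen genes (Fisher's exact test). However, EL replicate 1 then held 0 fibroblast and adipocyte markers, as did the PT libraries, and the exact permutation p of that list was 0.4. Of 26 leukocyte markers 1 gene (Cd4) and of 18 endothelial markers no gene was bound in at least 2 EL libraries, and none of either in PT. Of 16 lung epithelial markers, 3 were bound in at least 2 EL libraries and 2 in at least 2 PT libraries.

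Epithelial junction and keratin genes were bound in 15.6% ± 3.12 of 32 genes per EL library and 22.9% ± 10.05 per PT library (SD, n = 3; exact permutation p = 0.5, two-sided), a difference within the spread between replicates. Fisher's exact test gave adjusted p = 1 in EL (passed in 0 of 16 alternatives), 0.101 in PT (passed in 6) and 0.313 for EL-only against PT genes (passed in 2). Genes bound in all 6 libraries included Cldn3, Esrp1 and Cdh1, and Ocln was bound in 1 EL and 3 PT libraries. In lists of equal length the shares were 1.04% ± 1.80 in EL and 16.7% ± 1.80 in PT (exact permutation p = 0.1, two-sided). Mammary luminal and hormone-response genes were bound in 12.0% ± 6.93 of 25 per EL library and 12.0% ± 0 per PT library in full lists, and in 1.33% ± 2.31 (1, 0 and 0 genes) and 12.0% ± 0 (3 genes each) at equal list lengths (SD, n = 3; exact permutation p = 0.1, two-sided, adjusted p = 0.35). Trps1 and Tfap2a were bound in all 6 libraries, Csn3 in the 3 PT libraries alone and Tnfsf11 in 1 EL library.

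**Figure D4:**
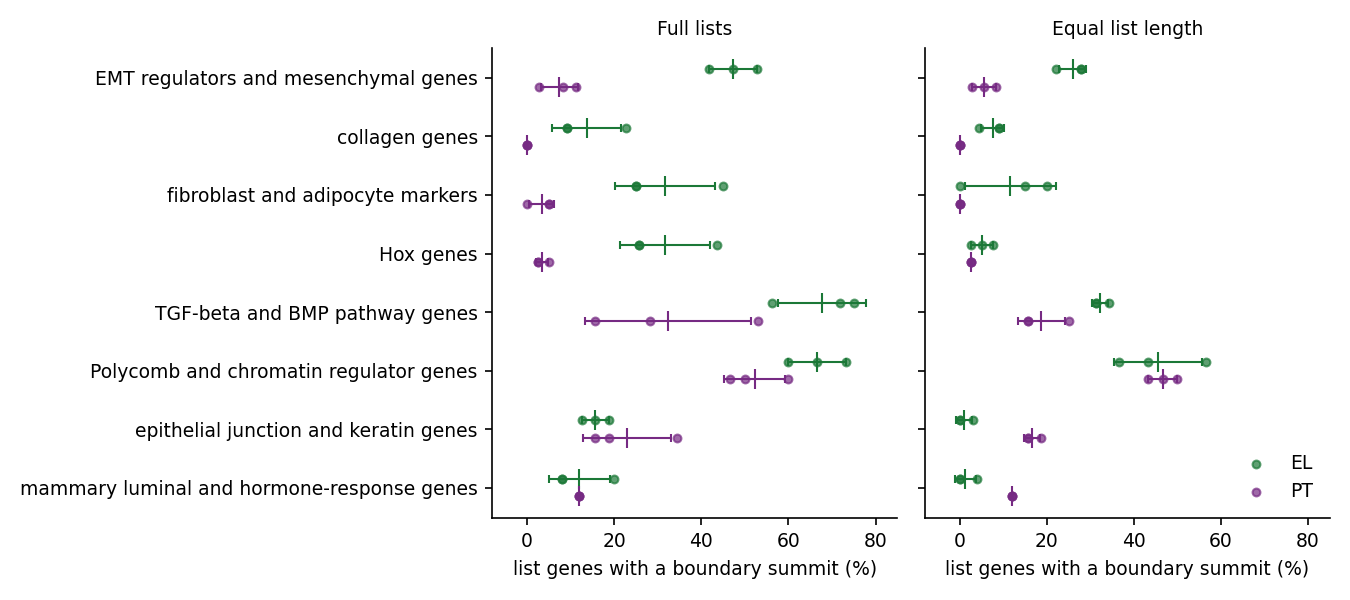
Share of the genes of 8 lists with a ZFP281 summit within 1 kb of a gene boundary (%), in full lists (left) and with equal list lengths (right); points are libraries, vertical ticks are group means and error bars are SD (n = 3). EMT and mesenchymal genes were bound at 47.2% in EL and 7.41% in PT in full lists, and epithelial genes at 1.04% and 16.7% with equal list lengths.

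In full lists 3 signalling and dormancy lists were bound above background in EL and PT. The dormancy list shares 5 genes with the TGF-beta and BMP list and 2 with the Wnt list, so its calls and theirs are not independent. The ERBB and MAPK list shares no gene with them. Genes of the TGF-beta and BMP pathway, which acts in EMT and growth arrest, were bound in at least 2 EL libraries for 24 of 32 genes (Fisher's exact test, odds ratio 18.3, adjusted p = 1.4e-13) and in at least 2 PT libraries for 8 (odds ratio 4.15, adjusted p = 0.0103), with Bmpr1a, Tgif1, Skil and Tgfb3 in all 6 libraries. The PT call was lost in 5 of 16 alternatives, among them equal list lengths (5 genes, odds ratio 3.06, Fisher's exact test, adjusted p = 0.119), without PT replicate 2 (0.0814) and without PT replicate 3 (0.0686). For ERBB and MAPK genes, which relay HER2 signals, the numbers were 17 and 10 of 36 (Fisher's exact test, adjusted p = 8.8e-06 and 0.00153), with Junb, Dusp4 and Braf among those in all 6. The PT call was lost without PT replicate 2 (Fisher's exact test, adjusted p = 0.0620) and with a score of at least 10 (0.424). For dormancy-associated genes they were 13 and 7 of 30 (Fisher's exact test, adjusted p = 0.000357 and 0.0236), with Cdkn2b, Dyrk1b, Bhlhe41 and Bhlhe40 in all 6, and the orphan receptor genes Nr2f1 and Nr2f2 in the 3 EL libraries and no PT library. At equal list lengths Nr2f2 was bound in 3 EL libraries and Nr2f1 in 0. Wnt pathway genes passed Fisher's exact test in EL (12 of 37, adjusted p = 0.0100) and not in PT (6 of 37, adjusted p = 0.142), and the test of the difference gave adjusted p = 1. The EL call was lost in 3 of 16 alternatives, equal list lengths included (Fisher's exact test, adjusted p = 0.0549). Fzd7, Gsk3b, Lrp6 and Fzd2 were bound in all 6 libraries. The differences of the TGF-beta and BMP, ERBB and MAPK, and dormancy lists also failed this exact test (adjusted p = 0.780, 0.780 and 0.746). Against random lists matched on gene length, a resampling alternative to the exact test added after seeing the data, the Wnt list in EL (adjusted p = 0.0617), and the TGF-beta and BMP (0.0613) and dormancy lists (0.0700) in PT, missed the threshold.

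Polycomb and chromatin regulator genes were bound above background in both groups. Lists matched on GC content were not run, so the part of sequence composition in this is unknown. In at least 2 libraries were bound 20 of 30 genes in EL (Fisher's exact test, odds ratio 12.2, adjusted p = 5.1e-10) and 16 in PT (odds ratio 14.3, adjusted p = 4.8e-10), with Kmt2a, Hdac2, Jarid2 and Ep300 in all 6 libraries. They made up a smaller part of the EL-only genes than of the PT genes (Fisher's exact test, odds ratio 0.102, adjusted p = 0.0339), a call that was lost in 10 of 16 alternatives, equal list lengths included (adjusted p = 1). Hox genes were bound in at least 2 EL libraries for 12 of 39 (Fisher's exact test, odds ratio 2.70, adjusted p = 0.0203) and in at least 2 PT libraries for 1 (adjusted p = 0.546), with Hoxa4 in all 6 libraries and Hoxa2 and Hoxb6 in 3 EL libraries and no PT library. At equal list lengths Hoxa2 and Hoxb6 were each bound in 0 EL libraries. The EL call was lost in 8 of 16 alternatives, among them leaving out EL replicate 1, 2 or 3 (Fisher's exact test, adjusted p = 0.0826, 0.221 and 0.271). The call of the Hox genes in the test of EL-only against PT genes (Fisher's exact test, odds ratio 16.7, adjusted p = 0.00426) was lost in 6 of 16 alternatives, equal list lengths included (adjusted p = 1), where the odds ratio in EL was 0.882. Without PT replicate 3 the adjusted p was 0.0673 for Polycomb and 0.0924 for Hox genes, so that no list passed.

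Of the remaining lists, olfactory receptor genes were bound below background by Fisher's exact test in EL (1 of 1110, adjusted p = 1.4e-72) and PT (0 of 1110, adjusted p = 1.4e-37), and keratin genes, of which 6 are also in the epithelial list, in EL (0 of 49, adjusted p = 0.00242; 0 of 49 in PT, adjusted p = 0.142). The keratin call in EL was lost in 3 of 16 alternatives, equal list lengths included (Fisher's exact test, adjusted p = 0.221). Pluripotency genes (5 and 2 of 30), cell cycle and replication genes (5 and 2 of 30), ribosomal protein genes (9 and 4 of 81), histone genes (7 and 6 of 39) and genes of the Zfp family (68 and 37 of 397) did not pass Fisher's exact test in either group, although Zfp genes passed in 1 of 16 alternatives in EL and 2 in PT, and histone genes in 1 in PT. The histone list missed the threshold in the exact test but passed against random lists matched on gene length in EL (adjusted p = 0.0012) and PT (adjusted p = 0.0014). Those random lists had a median of 1 bound gene in EL and 1 in PT, while 14.2% and 7.46% of all protein-coding genes were bound. They were drawn from all protein-coding genes, olfactory receptor genes included, so the pass rests on a low background. In all 6 libraries were the pluripotency gene Jarid2, the cell cycle genes Ccne1 and Cdk4, the ribosomal genes Rps18 and Rpl18, and the histone genes H3f3a and H4c9.

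By chromosome, the summit shares of the groups did not overlap for 6 of 21 chromosomes, where chance gives 2.1 (10%). Higher in EL were chromosomes 1, 18 and X, and higher in PT were chromosomes 7, 8 and 11. Chromosome 18 held 3.46% ± 0.147 of EL and 2.71% ± 0.296 of PT summits, and X 1.74% ± 0.0364 and 1.33% ± 0.199 (SD, n = 3). The exact permutation p was 0.1 and the adjusted p 0.35 for each, so none passed the correction. Without PT replicate 1 the groups did not overlap for 10 chromosomes. With 1 library fewer, non-overlap is more likely by chance, so 2.1 is not the chance value for that number.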

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

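The EL replicate 3 list held 4 summits outside chromosomes 1 to 19, X and Y, 2 of them on the mitochondrial genome, which is above the limit of 3 that a count of 0 allows. These summits entered no comparison. EL replicates 1 and 2 held 1 and 3 such summits and PT replicate 3 held 2. Groups of 3 libraries are too small for a search for outlying libraries, and the design has no second contrast.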

How the results depend on the processing

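No exact permutation test of 3 against 3 libraries could pass 0.05, so the side of the threshold says nothing about stability there; the signs of the EL minus PT differences in summit number, EMT and epithelial shares and library agreement did not change under the alternatives run. At equal list lengths the boundary share differed by -0.127 points (exact permutation p = 1) and the ratio of bound genes was 1.02 (exact permutation p = 0.6), so neither difference remained. The cause of the changes below was not tested, except where the rule itself sets the direction. Equal list lengths and stricter scores remove summits by construction. Leaving out a library loosens the rules for the shared, EL-only and PT-only classes, so those numbers could hardly fall. Tests of the difference between consensus sets, random lists matched on gene length and score percentiles were chosen after seeing the data.

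With a score of at least 10, regions in all 6 libraries, in EL only and in PT only numbered 755, 900 and 77, and genes 493, 250 and 5. At equal list lengths the regions were 996, 442 and 381, and the EL-only and PT-only genes 83 and 74. Merging within 50 bp gave 931 shared and 1087 EL-only regions. Regions above the 50th, 75th and 90th percentile of all 3 EL lists numbered 2716, 1378 and 558. Of these, 650, 182 and 31 (23.9%, 13.2% and 5.56%) had no PT summit. For the 3 PT lists they numbered 1127, 569 and 226, and 25, 5 and 1 (2.22%, 0.879% and 0.442%) had no EL summit. Most regions with high scores in 1 group thus held a summit in at least 1 library of the other. These percentiles come from lists of different lengths, so the groups cannot be compared by them. A window of 500 bp gave 278 EL-only and 6 PT-only genes, and 5 kb gave 1523 shared, 742 EL-only and 27 PT-only genes. All annotated genes gave 18 PT-only genes and 8 lists above background in PT, against 4.

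The Hox odds ratio in EL fell to 0.973 with a score of at least 10 and to 0.882 with equal list lengths, and the collagen odds ratio in EL rose to 2.34 (Fisher's exact test, adjusted p = 0.0119) over gene bodies and 5 kb around them; its adjusted p ranged from 0.0119 to 1. Lists that differed between the consensus sets numbered 3 in the main test, 1 with a score of at least 10, 1 with 500 bp, 5 with 5 kb, 5 with gene bodies and 1 with a summit in all 3 libraries. At equal list lengths 3 lists differed, of which 1, the EMT list, was among the 3 of the full lists.

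Leaving out each library gave 1995 to 3409 EL-only and 147 to 315 PT-only regions, 441 to 757 EL-only and 11 to 32 PT-only genes, 2 to 4 lists above background in PT (2 without PT replicate 2), 0 to 4 lists that differed (0 without PT replicate 3, 1 without EL replicate 3) and 6 to 10 chromosomes without overlap. PT-only regions numbered 253 without EL replicate 2. Chromosomes without overlap are more likely by chance with 1 library fewer, so their numbers cannot be set against that of the full design.

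With replicate numbers as a replicate block, the ratio of summit numbers was 2.38 (exact paired sign-flip p = 0.25, the smallest possible), so no paired test could pass 0.05 and no call changed. Same-numbered libraries did not deviate together (correlations -0.0721, 0.0153 and 0.0731), and not every library correlated best with its own number, so the numbers were not taken as pairs.

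Leaving out bins of 10 kb with 10 or more summits of 1 library removed no summit and gave no value. Equal list lengths give no summit number. Alternatives that need sequence were not run. Unknown depth limits every comparison of list lengths.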

Other observations

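All tests in this part except that of chromosome 4 copies and the other splits for gene lists were chosen after the result was seen.

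With equal list lengths, 74 genes were bound in the 3 PT and no EL library. They were led by Tkt, Adcy8, Pdcd2l and Krtcap3, and included the epithelial genes Cdh1, Cldn3, Cxadr and Prss8, the milk protein genes Lalba and Csn3, and the EMT list gene Sox4. In full lists Cdh1, Cldn3 and Sox4 were bound in all 3 EL libraries as well, Cxadr and Prss8 in 2, Lalba in 1 and Csn3 in 0. The 83 EL-only genes of this comparison included Mmp19, Pcolce, Mxra8, Tgfbr1 and Zeb1. These genes were picked after their values were seen.

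Several loci carried a run of regions found in all 3 EL and no PT library. Tns1 held 5 of them among 15 regions within the gene or 5 kb of it, Zeb2 5 among 13 and Nr2f1 4 among 5, where 10.03% of all regions were of this class. No gene of 2055 with at least 3 regions passed correction (exact hypergeometric test, lowest adjusted p = 0.953, at Nr2f1).

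Libraries agreed more within than between groups, and the EMT and mesenchymal genes were bound more in EL. List length as the whole account of both is argued against: with equal list lengths the within-group index still exceeded the between-group index by 0.205, and the EL library with the fewest EMT genes had 8 against at most 3 in PT. Fibroblast-like cells in the EL cultures are a candidate explanation for the EMT genes that the values do not decide. Outside the EMT list, 6 of 58 fibroblast, adipocyte and collagen genes were in the EL consensus and 0 in the PT consensus. Of all protein-coding genes, 14.2% were in the EL consensus and 7.46% in the PT consensus. All 6 belong to the fibroblast and adipocyte list of 20 genes, whose odds ratio in EL was 2.597 (Fisher's exact test, adjusted p = 0.112). The collagen genes outside that list added none, so the pooled share does not describe the fibroblast and adipocyte markers alone. At equal list lengths 0 to 4 of the 58 genes were bound per EL library and 0 per PT library. Mesenchymal change in the lesion cells could give the same values, so the explanations cannot be told apart here, and a difference between lesion stages stays open and untested.

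Only 10 splits of the 6 libraries exist, too few for a share under 0.05. For regions found in every library of a group and none of the other, 1 split, the real one, gave as many, with 2073 against at most 288 in the others. For genes the numbers were 434 against 141, again 1 split. For gene lists that differed in either direction they were 3 against 0, again 1 split.

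PT replicate 3 had few summits on chromosome 4. It retained 147 of 177 chromosome 4 regions found in both other PT libraries (83.1%) and 93.7% elsewhere (Fisher's exact test, adjusted p = 0.000464), the only 1 of 114 combinations of library and autosome to pass. List length is argued against, since with equal list lengths its chromosome 4 share was 5.04% (95% Wilson interval 4.301% to 5.90%) and those of PT replicates 1 and 2 were 7.70% and 7.28%. Fewer copies of chromosome 4 in that culture may account for it. Among regions of all 6 libraries, the score percentile of PT replicate 3 minus the mean of the other PT libraries was lower on chromosome 4 than on other autosomes. The difference of medians was -8.60 over 99 regions (permutation p = 7.0e-05 with 100000 permutations, two-sided), the largest in size of the 114 combinations. Lower scores and fewer summits can be the same drop in signal, so this test cannot tell fewer copies from weaker binding. In full lists the chromosome 4 share was 5.35% in PT replicate 3 and 7.00%, 6.72% and 6.46% in EL replicates 1, 2 and 3. PT replicates 1 and 2, the reference of the test, lay above every EL library, at 7.70% and 7.57%. Neighbouring regions are not independent, the input was not analysed here, and the hypothesis was found and tested on the same lists.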
